A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

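RNA abundance was measured on 6 Affymetrix Yeast Genome 2.0 arrays, each hybridised with biotin-labelled total RNA from Saccharomyces cerevisiae grown on minimal glucose medium in fermenters held at pH 5.0 and sampled in mid exponential phase. The arrays fall into 4 groups by their labels: the evolved strain 62A (1 array), the evolved strain 62B (2 arrays), the evolved strain 62C (1 array) and the unevolved reference strain CEN.PK113-7D (2 arrays). The labels do not say whether the paired arrays came from separate cultures. All p-values therefore measure only the spread between these arrays, or between these strains, which may be technical.

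The values used were the deposited log2 expression values of the series table, which the authors made by RMA with the affy package, per the submitters' processing notes. Versions of those tools are not given in the sources used here, nor is the set of arrays that entered the normalization together. No value was rescaled, and 0 columns of the table were left unused. The table held 10928 probe sets. The platform annotation named a gene for 7245 of them and no gene for 3683. Of the named probe sets, 5498 matched 1 S. cerevisiae gene each, 1746 belonged to another yeast species and 1 named several genes. Gene symbols were updated through gene identifiers to the current RefSeq gene table of the species, which changed 12 symbols. The genome build is not given in the sources used here, and no coordinates are printed. For the 47 genes with several probe sets, the probe set with the highest mean was kept, and 12 of these genes had probe sets whose changes differed in sign. The tested set held 5449 genes. For 109 of them the kept probe set is of the kind that can hybridise to related genes, and its value can include those relatives.

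Background was taken from the probe sets of the other species, whose 95th percentile was 5.07 on the log2 scale (median 4.98, SD 0.053). Between 96.8% and 97.3% of the tested genes lay above this level on each array. The number of arrays limits the precision, and no read depth applies.

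All tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05. The evolved class was compared with the reference by treating each evolved strain as 1 sample: 62A, the mean of both 62B arrays, and 62C were set against 2 reference arrays, which left 3 residual degrees of freedom. The reference, also 1 strain, thus counted as 2 samples. Its spread between arrays was pooled with the spread between evolved strains. Each strain was compared with the reference, and with the other strains, in a fit with 1 term per strain over all 6 arrays. That fit had 2 residual degrees of freedom, and its spread came from the 62B pair and the reference pair, so the single arrays of 62A and 62C were assumed to vary like those pairs. Differences among the 3 evolved strains were tested with a moderated F statistic. Errors given as ± are standard errors of these fits unless named as SD.

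Shifts of 37 gene lists, fixed before the data were examined and holding 960 different measured genes, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The estimated form is also limited to the residual degrees of freedom of the fit, 3 for the class and 2 for the strains. It therefore had little power to pass any list. Adjustment ran over the 37 lists for the class and over the lists and strains together for the single strains. Correlations of strain effects were set beside the mean of 100 simulations in which unchanged strains shared the reference arrays. Calls shared by strains were set beside 100 simulations, added after the data were seen, in which the called effects were placed on unrelated genes in each strain and the reference arrays were shared. The fits were tested on simulated arrays with the real means and fitted variances. In the class comparison of 5449 genes, 100% of the 67 genes changed by 0.5 on the log2 scale were recovered. The same run changed 67 further genes by 1 and 66 by 2, and its 17 false calls are those of the whole run. Those simulated strains did not differ from one another, unlike the real ones.

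The genes named were chosen by a rule fixed before the data were examined. It took 12 genes in each direction for the evolved class, among those past the threshold with all 4 evolved arrays on the same side of both reference arrays, and 4 in each direction per strain. It also took the 8 genes with the smallest p among strains and 3 members per list. GAL1, GAL2, GAL3, GAL7, GAL10, GAL80, RAS1, RAS2 and CYR1 were always named, while GAL4 was not analysed here because the platform annotation names no probe set for it. Genes below background were left out of the ranking. Some genes are named outside this rule, and the text lists them or says so.

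Alternatives changed these choices: the treatment of the 62B arrays, the replicate number as a block, quantile normalization, median centring, a background filter, all probe sets, the variance prior, the threshold, a minimum fold of 2, each array left out, the camera correlation and separate reference arrays. Each changed a single choice, except that the block fits of the class also took the 62B arrays as separate samples. A block for the hybridization controls and list tests between strains were added after the data were seen. Figures were drawn with matplotlib 3.10.9.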

Results

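The study profiled glucose-grown cultures of 3 Saccharomyces cerevisiae strains that had been evolved on galactose, named 62A, 62B and 62C, together with their unevolved reference strain CEN.PK113-7D. The comparison asks how strains adapted to galactose express their genes when they are returned to glucose. Expression of 5449 genes was compared over 6 arrays: 1 of 62A, 2 of 62B, 1 of 62C and 2 of the reference. Arrays of the same strain were close. The SD of the log2 difference over genes was 0.0695 between the 62B arrays and 0.0956 between the reference arrays, and 0 genes differed by over 2-fold in either pair. Between an evolved and a reference array this SD ranged from 0.249 to 0.366. Median log2 values of the tested genes lay between 7.30 and 7.34 on all arrays. The 3' minus 5' log2 difference over 8 control genes is a measure of RNA integrity. It was 2.01 and 2.05 on the 62B arrays, 1.89 on 62A, 1.73 on 62C, and 1.90 and 1.84 on the reference arrays. A separate pair of ACT1 control probe sets gave 1.58 and 1.73 on 62B, 1.49 on 62A, 1.41 on 62C, and 1.40 and 1.27 on the reference arrays. By this ACT1 pair all evolved arrays lay above both reference arrays. RNA quality was not tested as a cause of the differences between evolved strains and reference.

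In the evolved strains 5 of 34 stress-induced genes and 1 of 21 glycogen and trehalose genes rose, and 22 of 49 amino acid biosynthesis genes fell, against the reference. These 3 lists passed camera, each with an adjusted p = 0.682 with an estimated correlation. YGP1 (YNL160W), a secreted glycoprotein gene induced by nutrient limitation, was 6.12-fold higher (log2 change 2.61 ± 0.35, 3 strains against 2 reference arrays, limma adjusted p = 0.0364). TSL1, a subunit of the trehalose synthase complex, was 4.17-fold higher (2.06 ± 0.33). DIP5, a permease for acidic amino acids, and SUL1, a sulfate permease, were both at 0.389 of the reference level (log2 changes −1.36 ± 0.12 and −1.36 ± 0.13, both limma adjusted p = 0.0329). In this comparison 107 genes passed the threshold upward and 152 downward, and each of these 259 genes also passed in the same direction in all 3 strains tested singly. The single tests used the same arrays and are no independent support.

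Other genes that rose included TMA10 (log2 change 1.91 ± 0.31), STF2 and STF1, which act on the mitochondrial ATP synthase (1.90 ± 0.30 and 1.07 ± 0.19), the cell wall protein SED1 (1.59 ± 0.17) and the mitochondrial lactate dehydrogenase CYB2 (1.57 ± 0.23). SDH6 (1.39), PHM7 (1.28), PNS1 (1.26), the small heat shock protein HSP42 (1.25) and the mitochondrial membrane protein SYM1 (1.20) completed the 12 named upward genes, with limma adjusted p between 0.0241 and 0.0477 over the 12. Among the genes that fell were 3 further amino acid permeases, BAP2 (−1.14 ± 0.13), GNP1 (−1.04 ± 0.18) and BAP3 (−0.85 ± 0.07). The others were the glycerol phosphatase GPP1 (−1.08), the NADPH oxidoreductase OYE2 (−1.05), the IMP dehydrogenase IMD2 (−0.87), the alcohol dehydrogenase ADH5 (−0.86 ± 0.05), SNZ1 of vitamin B6 synthesis (−0.85), the glycine decarboxylase subunit GCV2 (−0.80) and AAD4 (−0.80). The probe sets of IMD2 and AAD4 can also hybridise to related genes.

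**Figure D1:**
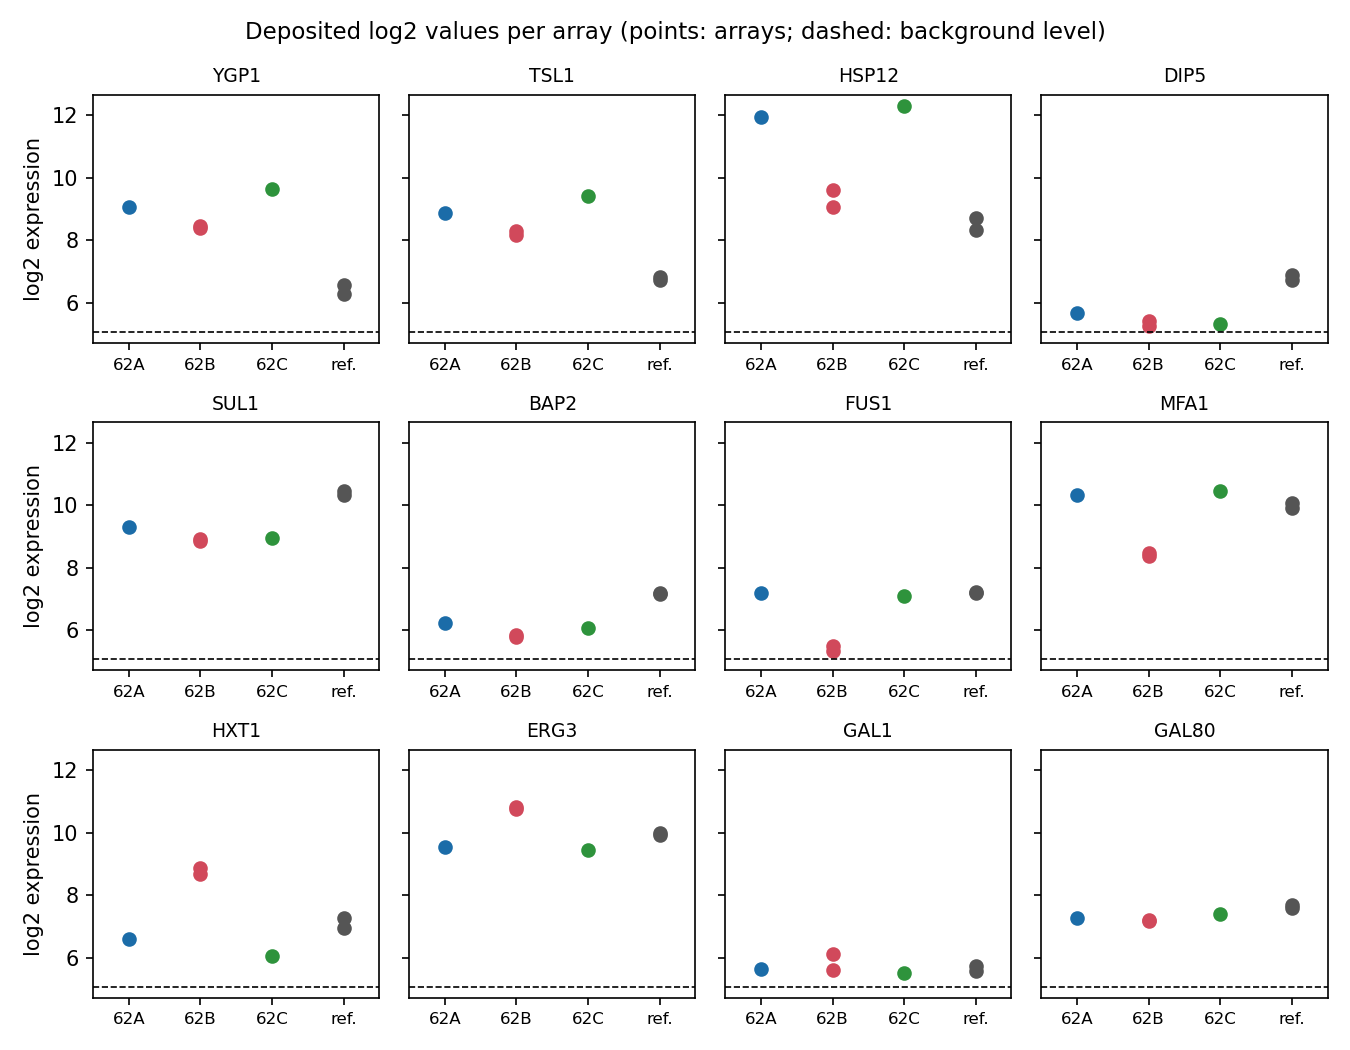
Deposited log2 expression (y axis) of 12 genes in 62A, 62B, 62C and the reference (x axis), with 1 point per array and a dashed line at the background level of 5.07. YGP1 and TSL1 lay above, and DIP5, SUL1 and BAP2 below, both reference arrays in all 4 evolved arrays, whereas FUS1 and MFA1 were low in 62B and HXT1 and ERG3 were high there.

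Biosynthetic gene lists were shifted downward in the evolved strains. Of 49 measured genes of amino acid biosynthesis, 22 fell and 0 rose over all genes tested, and 40 fell when adjusted over the list alone (list median −0.38, camera adjusted p = 6.18e-17). ASN1 (−0.64 ± 0.07), ARO4 (−0.51 ± 0.05) and GLN1 (−0.49 ± 0.06), of asparagine, aromatic amino acid and glutamine synthesis, were among them. Of 20 genes of purine and one-carbon metabolism, 11 fell and 17 fell when adjusted over the list alone (median −0.49, camera adjusted p = 8.25e-09), including ADE4 (−0.55 ± 0.06) and MTD1 (−0.57 ± 0.06). Ribosome biogenesis (3 of 63 fell, 3 adjusted over the list alone, median −0.24, camera adjusted p = 7.49e-08) and methionine and sulfur assimilation (1 of 25 fell, 10 adjusted over the list alone, median −0.29, camera adjusted p = 3.27e-06) were shifted the same way. So were the proteasome (0 of 32 fell, 9 adjusted over the list alone, median −0.20, camera adjusted p = 1.71e-05) and RNA polymerases I and III (1 of 21 fell, 4 adjusted over the list alone, median −0.22, camera adjusted p = 0.00759). With an estimated correlation the adjusted p of each of these 6 lists was 0.682.

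Lists of stress, reserve carbohydrate and mitochondrial genes were shifted upward. Of 34 stress-induced genes of the Msn2/4 type, 5 rose and 17 rose when adjusted over the list alone (median 0.65, camera adjusted p = 2.53e-11). HSP104, a disaggregase, was among them (0.99 ± 0.16). Of 21 glycogen and trehalose genes, TSL1 alone rose over all genes tested and 12 rose when adjusted over the list alone (median 0.70, camera adjusted p = 3.65e-08). The respiratory chain (2 of 25 rose, 13 adjusted over the list alone, median 0.23, camera adjusted p = 1.81e-08), the ATP synthase (3 of 17 rose, 7 adjusted over the list alone, median 0.38, camera adjusted p = 8.53e-07) and mitochondrial ribosomal proteins (5 of 69 rose, 10 adjusted over the list alone, median 0.14, camera adjusted p = 5.17e-08) were shifted upward too. MRP21 (0.53 ± 0.06) and COX9 (0.39 ± 0.05) were members that rose. In the ATP synthase list the 3 that rose were STF2 and STF1, which act on the enzyme, and TIM11 (0.39 ± 0.06). All 17 genes of that list had changes above 0. Among them ATP1, ATP2, ATP3 and ATP5, named outside the rule for named genes, had changes from 0.07 to 0.13 and did not pass. Histone and S phase genes were shifted upward (1 of 18 rose, 3 adjusted over the list alone, median 0.17, camera adjusted p = 3.65e-05), with HTA1 at 0.38 ± 0.06. With an estimated correlation the adjusted p of each of these 6 lists was 0.682.

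The cell wall list passed the test upward although its median was 0.0042. Its camera adjusted p was 0.0407 and its adjusted p = 0.682 with an estimated correlation. SED1 and CWP1 (1.06 ± 0.14) were among 3 of 30 genes that rose, while PIR1 (−0.35 ± 0.06) fell. Whether these few genes carried the call was not tested. Cytosolic ribosomal proteins also passed upward (camera adjusted p = 0.036), with a median of 0.028 over 127 genes of which 0 rose and 1, RPS0B (−0.28 ± 0.05), fell. The adjusted p was 0.699 for that list with an estimated correlation.

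The galactose pathway genes were not shifted as a list on glucose (8 genes, 0 past the threshold, median −0.09, camera adjusted p = 0.421). GAL1, GAL2, GAL3, GAL7 and GAL10 had reference levels of 5.67, 5.28, 5.43, 5.43 and 5.75 on the log2 scale, against a background of 5.07, and their log2 changes lay between −0.16 and 0.02. Of these 5 genes tested in single strains, GAL3 alone passed, downward in 62B (−0.27 ± 0.05). PGM2, a phosphoglucomutase of the list, had a change of 1.94 in the class that did not pass (limma adjusted p = 0.0776). It passed the threshold upward in each strain tested singly (2.15 ± 0.07 in 62A, 0.98 ± 0.06 in 62B and 2.68 ± 0.07 in 62C). PGM1, the other phosphoglucomutase of the list, named outside the rule, had a change of −0.22 in the class (limma adjusted p = 0.293). It passed downward in 62A (−0.30) and 62C (−0.35) only. GAL80, the repressor of the pathway, had a log2 change of −0.35 ± 0.07 (limma adjusted p = 0.0604) and passed the threshold downward in each strain tested singly. CYR1, the adenylate cyclase, rose (0.36 ± 0.07, limma adjusted p = 0.0466). RAS1 had a change of −0.34 ± 0.07 (limma adjusted p = 0.0617) and passed downward in each strain tested singly (−0.30, −0.46 and −0.28), and RAS2 had a change of 0.17 ± 0.14 (limma adjusted p = 0.449) and passed upward in 62A (0.19) and 62C (0.40) only.

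The other lists did not pass in this comparison. Their medians were 0.0080 for hexose transport (0 of 17 genes passed), −0.08 for glucose sensing and repression (1 of 21 rose), 0.03 for Ras/cAMP/PKA signalling (1 of 21 rose), −0.16 for glycolysis (2 of 16 fell) and −0.07 for ethanol and acetate metabolism (2 of 19 fell). They were 0.14 for glycerol metabolism (2 of 12 rose and 1 fell), 0.02 for gluconeogenesis and the glyoxylate cycle (0 of 17), 0.07 for the TCA cycle (2 of 19 fell), −0.09 for the HAP complex and regulators of respiration (1 of 13 fell) and −0.15 for the pentose phosphate pathway (1 of 12 fell). Sucrose, maltose and other sugar use (0.03, 0 of 12), Hsf1-type chaperones (−0.14, 2 of 20 rose and 3 fell), nitrogen catabolite repression (−0.12, 1 of 26 rose), ergosterol biosynthesis (−0.17, 1 of 26 fell) and fatty acid and phospholipid synthesis (−0.08, 1 of 24 rose) did not pass either. Neither did peroxisomes and fatty acid oxidation (0.05, 0 of 18), the phosphate response (−0.06, 1 of 19 rose), iron, copper and zinc uptake (−0.13, 1 of 26 rose), thiamine and vitamin synthesis (−0.07, 2 of 19 fell), mating and pheromone response (−0.18, 0 of 25), sporulation and meiosis (−0.02, 0 of 19) or cell adhesion and filamentation (0.01, 0 of 11).

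These class counts rested on few arrays. Without either reference array 0 genes passed in limma, without 62A 3 rose and 3 fell, without 62C 59 rose and 40 fell, and with strain as a random block over all 6 arrays 10 rose and 11 fell. In the full comparison 1555 genes had an unadjusted p under 0.05.

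Each strain was then compared with the reference singly. In 62C, GPH1, the glycogen phosphorylase, was higher by 3.99 ± 0.14 on the log2 scale and HSP12, a membrane-protecting stress protein, by 3.77 ± 0.20. In 62A the same genes were higher by 3.24 ± 0.14 and 3.42 ± 0.20, and in 62B by 0.69 ± 0.12 and 0.82 ± 0.16 (limma adjusted p below the threshold in each strain). HXK1, a hexokinase repressed by glucose, was higher by 2.75 ± 0.20 in 62A, 1.18 ± 0.16 in 62B and 3.47 ± 0.20 in 62C. In 62B the largest rises among the named genes were those of HPF1, a cell wall mannoprotein (2.90 ± 0.06), YGP1 (1.99 ± 0.08), SED1 (1.83 ± 0.05) and the low-affinity glucose transporter HXT1 (1.66 ± 0.10).

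The largest falls in 62B were those of the Ty1 Gag open reading frame YAR010C (−1.82 ± 0.07), whose probe set can hybridise to other Ty1 copies, the cell fusion gene FUS1 (−1.78 ± 0.06), SRD1 (−1.66 ± 0.08) and BNA2 (−1.64 ± 0.05), the first enzyme of NAD synthesis from tryptophan. In 62A they were those of DIP5 (−1.15 ± 0.09), the propionate-induced PDH1 (−1.11 ± 0.06), SUL1 (−1.11 ± 0.07) and GPP1 (−0.96 ± 0.07). In 62C they were those of ATR1, a multidrug transporter (−1.60 ± 0.07), DIP5 (−1.47 ± 0.09), SUL1 (−1.46 ± 0.07) and PDH1 (−1.44 ± 0.06). Counts of calls do not rank the strains by distance from the reference, because 62B had 2 arrays, and so smaller standard errors, and 62A and 62C had 1 each. In all, 546 genes rose and 811 fell in 62A, 1094 rose and 1161 fell in 62B, and 803 rose and 1270 fell in 62C. Of these, 48, 19 and 89 rose and 3, 22 and 13 fell by at least 2-fold in 62A, 62B and 62C. Without either 62B array 445 genes fell in 62A, and in 62B 684 and 589 rose and 596 and 624 fell.

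**Figure D2:**
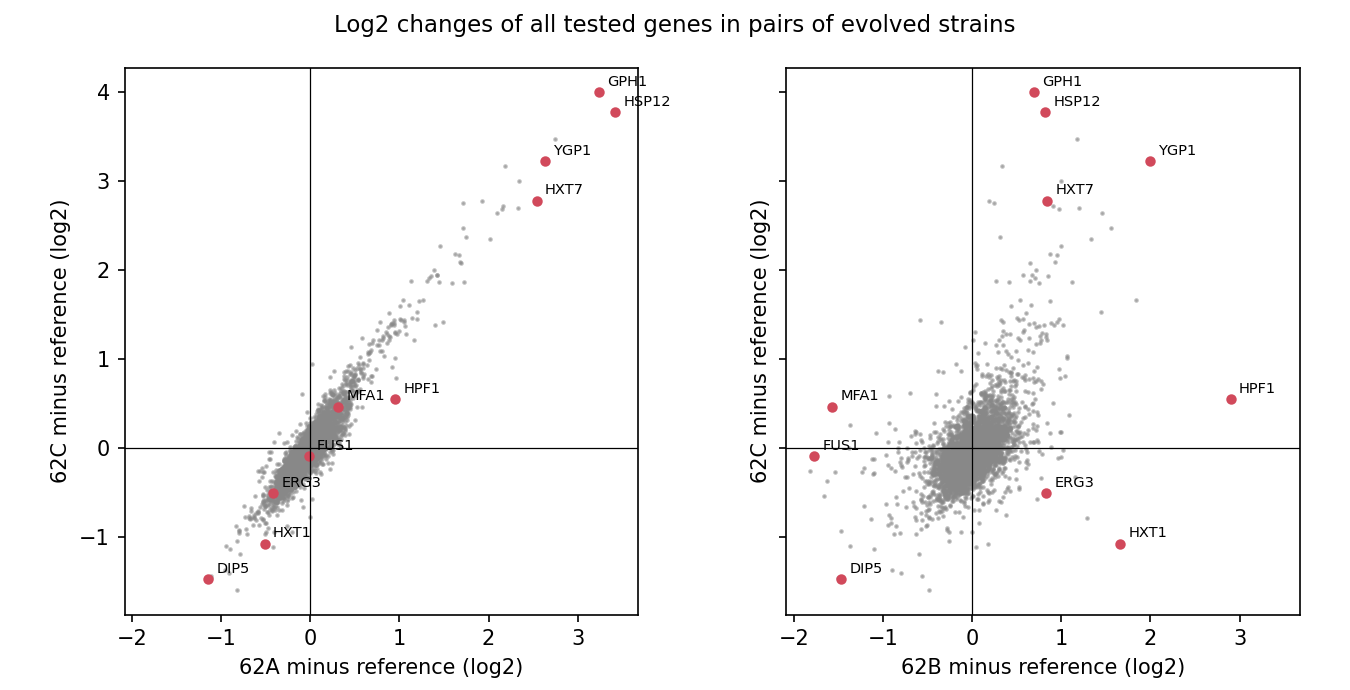
Log2 change from the reference of all 5449 genes in 62C (y axes) against 62A (left x axis) and 62B (right x axis), with 1 grey point per gene and 10 labelled genes in red. Points lie near a line for 62A and 62C (r = 0.937 over genes), while HPF1, HXT1, MFA1, FUS1 and ERG3 stand apart in 62B.

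The stress-induced list rose in all 3 strains, with 26 of 34 genes up in 62A (median 0.67), 23 in 62B (0.38) and 29 in 62C (1.10). Glycogen and trehalose genes rose likewise, with 17, 14 and 19 of 21 genes up (medians 0.64, 0.35 and 1.05). Respiratory chain genes rose in 15, 12 and 20 of 25 cases (medians 0.22, 0.14 and 0.40) and ATP synthase genes in 12, 7 and 17 of 17 cases (medians 0.38, 0.17 and 0.59). Amino acid biosynthesis fell in 40, 40 and 44 of 49 genes (medians −0.39, −0.30 and −0.49), purine and one-carbon metabolism in 18, 17 and 19 of 20, methionine and sulfur assimilation in 16, 14 and 20 of 25, and ribosome biogenesis in 24, 25 and 56 of 63. Few members moved the other way: 1 stress-induced gene fell in 62A and 1 in 62C, 1 respiratory chain gene fell in 62C, 2 ATP synthase genes fell in 62B, and in 62B 1 purine gene, 1 methionine gene and 3 ribosome biogenesis genes rose. Each of these 8 lists passed camera in each strain. With an estimated correlation 0 lists passed in any strain, and the adjusted p of these calls lay between 0.541 and 0.864. That form rests on 2 residual degrees of freedom, so its failure to pass does not mean that correlated members undo the shifts.

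Mitochondrial ribosomal proteins rose in 22 of 69 cases in 62A and 48 in 62C (medians 0.14 and 0.29), while in 62B 17 rose and 16 fell. That list did not pass in 62B. TCA cycle genes (11 of 19 rose and 3 fell, median 0.25) passed in 62C, as did sucrose, maltose and other sugar use (4 of 12 rose, median 0.06). The proteasome list passed downward in 62A (13 of 32 fell) and 62B (24 of 32 fell), and RNA polymerases I and III passed downward in 62A (10 of 21 fell and 2 rose) and 62C (15 of 21 fell). Histone and S phase genes passed upward in 62A (3 of 18 rose) and 62C (12 of 18 rose and 1 fell), and cytosolic ribosomal proteins in 62C (1 of 127 rose and 2 fell, median 0.049). The adjusted p of these list calls with an estimated correlation lay between 0.541 and 0.795.

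Genes of ergosterol synthesis, the yeast sterol, moved in opposite directions. In 62B 15 of 26 rose and 4 fell (median 0.20, camera adjusted p = 0.000722), while 20 of 26 fell in 62A (median −0.32) and 23 of 26 in 62C (median −0.45). ERG3, a sterol desaturase, was higher by 0.83 ± 0.05 in 62B and had changes of −0.42 ± 0.06 in 62A and −0.51 ± 0.06 in 62C. ERG28, ERG24 and ERG2 had changes of 0.40, 0.52 and 0.43 in 62B and of −0.44, −0.46 and −0.48 in 62C. ERG10, the first enzyme of the route, fell in all 3 strains (−0.80, −0.29 and −0.92). The 3 list calls had an adjusted p between 0.541 and 0.581 with an estimated correlation. Among the evolved strains the ergosterol medians ran in the same order as the 3' minus 5' control differences (2.01 and 2.05 in 62B, 1.89 in 62A and 1.73 in 62C), and the stress-induced medians ran in the reverse order. In these control differences the reference arrays (1.90 and 1.84) do not follow that order. There 62A lay between them, while its ergosterol genes fell and its stress-induced genes rose. By the ACT1 pair 62A (1.49) and the other evolved arrays lay above both reference arrays (1.40 and 1.27). The place of 62A between the reference arrays therefore does not hold for the ACT1 pair.

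Mating and pheromone response genes fell in 62B, in 19 of 25 cases over all genes tested and 21 when adjusted over the list alone (median −0.41, camera adjusted p = 6.72e-10, and adjusted p = 0.541 with an estimated correlation). MFA1, which encodes the a-factor pheromone, had a change of −1.58 ± 0.06, and BAR1, the protease that degrades alpha factor, of −1.12 ± 0.05. In 62A 6 of the 25 genes rose and 1 fell, and in 62C 9 rose and 4 fell, with medians of 0.0044 and −0.0071. Glycolysis genes also fell in 62B (12 of 16 fell and 2 rose, median −0.24, camera adjusted p = 0.00168, and adjusted p = 0.541 with an estimated correlation), with PFK1 at −0.53 ± 0.05 and ENO1 at −0.49 ± 0.05, while GLK1 rose (0.87 ± 0.07). Thiamine and vitamin synthesis passed downward in 62B (8 of 19 fell and 2 rose, median −0.11, camera adjusted p = 0.0335, and adjusted p = 0.694 with an estimated correlation). The 62B arrays had the highest 3' minus 5' control differences, 2.01 and 2.05.

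**Figure D3:**
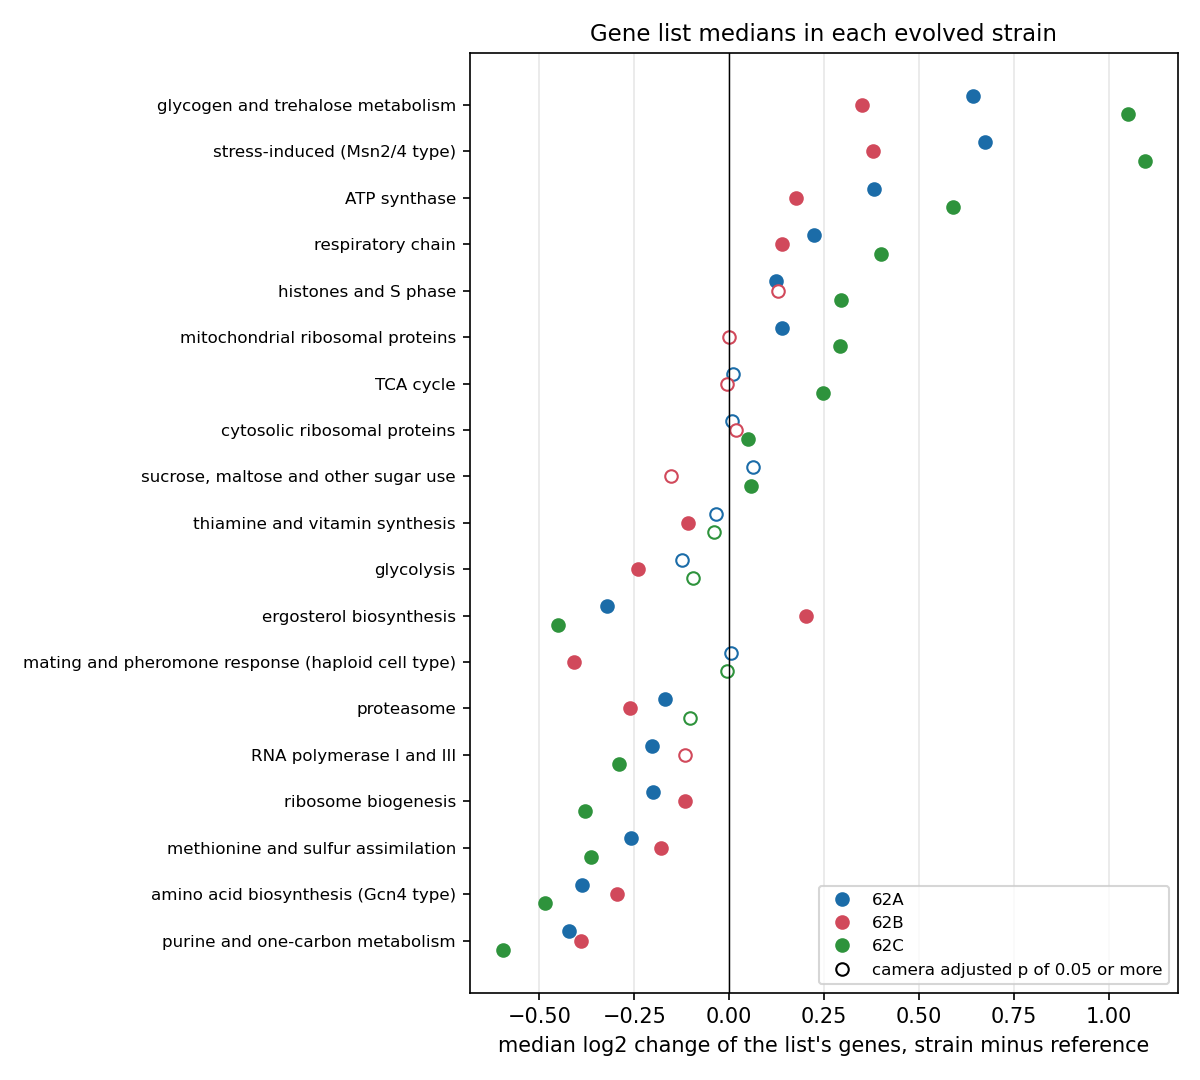
Median log2 change from the reference (x axis) of the gene lists that passed camera in at least 1 strain (y axis), for 62A, 62B and 62C, with filled points for a camera adjusted p under 0.05 at the preset correlation and open points otherwise. Stress-induced and glycogen genes lie to the right in all 3 strains, and ergosterol synthesis lies at 0.20 in 62B against −0.32 and −0.45 in 62A and 62C.

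Tested directly, 1571 genes differed among the 3 evolved strains. HPF1, ATF2, SSP1, DDR2, MFA1, DCS2, FUS1 and BNA5 had the smallest p. The alcohol acetyltransferase ATF2 had changes of −0.63 ± 0.07 in 62A, 1.29 ± 0.05 in 62B and −0.79 ± 0.07 in 62C, while the stress gene DDR2 rose by 2.18 ± 0.09, 0.34 ± 0.08 and 3.16 ± 0.09. Between 62B and 62C 1829 genes differed, between 62A and 62B 880, and between 62A and 62C 132. Without 62B replicate 1 or 2, 626 or 705 genes differed among the 3 strains, 959 or 1044 between 62B and 62C and 342 or 367 between 62A and 62B. Without either reference array 2366 differed among the 3 strains and 1493 between 62A and 62B. The count for 62A and 62C was 19 without either 62B array, 432 without either reference array, 272 with the replicate block and 0 when all probe sets were tested.

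The effects of 62A and 62C correlated at r = 0.937 across genes, those of 62A and 62B at 0.651 and those of 62B and 62C at 0.561. Genes are not independent replicates. Unchanged strains that shared the reference arrays gave 0.331, 0.407 and 0.406 in simulation. Noise of the shared reference arrays is part of that simulation. A state common to both reference arrays is not, and part of the excess may come from it. With a different reference array for each strain the values ranged from 0.877 to 0.909, from 0.561 to 0.639 and from 0.475 to 0.574. The covariance exceeded the simulated one by 0.0826, 0.0423 and 0.0489, respectively. Genes that rose in both 62A and 62C numbered 467 and those that fell in both 706, where lists drawn independently would share 80.5 and 189, and 1 gene moved in opposite directions. Between 62B and 62C 467 and 589 were shared (161 and 271 if drawn independently), and 120 genes moved in opposite directions. Between 62A and 62B 411 and 532 were shared (110 and 173 if drawn independently), and 47 moved in opposite directions. Because the calls share the reference arrays, strains with effects on unrelated genes were also simulated against shared reference arrays. In 100 simulations at most 102 and 201 genes were shared between 62A and 62C, 177 and 275 between 62B and 62C, and 126 and 194 between 62A and 62B. A state shared by both reference arrays is not part of that simulation.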

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

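The results here stand out because a test of the difference between strains passed its threshold. All tests of explanations in this part were chosen after the result was seen, except the test of Ste12-dependent genes. Of 195 named genes, 104 differed among the 3 evolved strains, and of all genes 1571 did. Pairs of strains differed in 880 genes (62A and 62B), 132 genes (62A and 62C) and 1829 genes (62B and 62C). Values are given for the 8 named genes with the smallest p among strains, for the 12 named genes called in opposite directions in different strains, and for lists between 62B and 62C, the pair with the most differing genes. The other differing genes and lists are given only as counts. PRM5, PRM6, ANB1, TIR1, TIR2, TIR3, TIR4, DAN1, DAN2, DAN3, HXT2, HXT3 and HXT4 are named below outside the rule for named genes, as members of the tests of explanations.

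As 62B minus 62C on the log2 scale, HPF1 differed by 2.35, HXT1 by 2.74, ATF2 by 2.08, FUS1 by −1.68, SSP1 by −1.62, DDR2 by −2.82, MFA1 by −2.04, DCS2 by −2.05, BNA5 by −1.38 and MAL32 by −1.76. STR3 differed by 0.84, ERG6 by 0.72, ERG28 by 0.84, ERG3 by 1.34, ERG5 by 0.81, ERG24 by 0.98 and ERG2 by 0.91. Among the lists, 17 differed between 62B and 62C, 14 between 62A and 62B and 16 between 62A and 62C by camera at the preset correlation, and 0 with an estimated correlation. The 62B minus 62C median difference was −0.80 for glycogen and trehalose, −0.73 for stress-induced genes, −0.49 for the ATP synthase, −0.41 for sucrose, maltose and other sugars, −0.38 for mating, −0.29 for the TCA cycle, −0.25 for the respiratory chain, −0.24 for mitochondrial ribosomal proteins, −0.13 for histones, −0.13 for the proteasome, −0.11 for glycolysis and −0.088 for sporulation. It was 0.65 for ergosterol, 0.26 for ribosome biogenesis, 0.25 for methionine and sulfur, 0.23 for RNA polymerases I and III and 0.17 for amino acid biosynthesis.

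Pheromone-response genes were lower in 62B. A change to the a/alpha cell type, or a mixture with such cells, was tested on 11 haploid-specific and a-specific genes, assuming a common fall. Their changes spanned 1.68 on the log2 scale (from 0.11 to −1.58, median standard error 0.055). Genes repressed to different degrees would fall by different amounts, so that span decides nothing. The 6 haploid-specific genes stayed at least 1.46 above background, and a change of cell type stays open. Lower output of Ste12-dependent transcription was tested on 13 such genes outside the list, and their median of −0.0019 lay at the 57.2th percentile of 10000 random lists. By the rule set before the values were seen, a median at or above the 2.5th percentile goes against this explanation. A reading as undecided was not part of that rule. It was taken because 5 of the 13 fell (PRM5 by −0.94) and 1 rose, and the gene at the median, PRM6, lay below background. Over all 5449 genes, 1161 fell and 1094 rose in 62B. Lower Ste12 output is therefore left open despite the rule, as is an untested genetic difference of 62B. RNA quality of the 62B arrays cannot be told apart from the pattern: the 3' minus 5' control difference exceeded the reference by 0.162 (SD 0.124 over 8 genes), less than the list median of −0.41 in size, but the place of each probe in its transcript was not used here.

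Stress and reserve-carbohydrate genes were higher in 62A and 62C than in 62B. Glucose exhausted at sampling would raise the 17 gluconeogenesis and glyoxylate genes, whose median over 62A and 62C was 0.0067 (SD 0.12), against 0.83 for the stress list, and the labels place sampling in mid exponential phase. Lower residual glucose that still represses those genes cannot be told apart from a change of signalling in the strains: HXT2, HXT4 and HXT7 less HXT1 and HXT3 came to 1.78 in 62A and 62C and −0.99 in 62B, which either would allow, and no glucose values were analysed here. HXT7 carried most of the rise (2.54 in 62A and 2.77 in 62C), while HXT2 (−0.05) and HXT4 (0.14) did not pass in 62A and rose by 0.28 and 0.25 in 62C. HXT1 and HXT3 fell in 62A (−0.51 and −0.49) and in 62C (−1.08 and −1.08), which also entered the contrast. The 3' minus 5' control differences (2.01 and 2.05 in 62B, 1.89 in 62A, 1.73 in 62C) ran in the reverse order of the stress medians. By these differences 62A lay between the reference arrays (1.90 and 1.84) with a stress median of 0.67. The list rose in 62B too (0.38). By the ACT1 pair, however, 62A (1.49) and the other evolved arrays lay above both reference arrays (1.40 and 1.27). RNA quality was not tested for this pattern and stays open, with a single array each of 62A and 62C.

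Ergosterol genes were higher in 62B and lower in 62A and 62C. Further scaling of the arrays did not remove the 62B rise. Its median was at least 0.175 under quantile normalization and median centring, against 0.20 as deposited (standard error 0.072). The deposited values were already normalized by RMA, with array medians between 7.30 and 7.34, so these steps could move it little. The falls in 62A and 62C were not part of this test. Lower oxygen in the 62B cultures was tested on 10 genes induced without oxygen, whose median lay at the 57.0th percentile of random lists. Of them 3 rose, TIR3 by 0.74 among them, and 1 fell, while ANB1 (0.006) and DAN1 (−0.03) were near 0. Over all 5449 genes 1094 rose and 1161 fell in 62B, so such passing members are no sign of lower oxygen. Under the rule used, any member that rose left the question undecided. That rule could seldom go against lower oxygen, which stays open without support from these genes as a group. An earlier form of that test left out TIR3, whose rise had been seen, and took in TIR1, TIR2 and TIR4, which had been seen near 0; all measured members of the DAN and TIR families were then used, and DAN2 and DAN3 were not measured. RNA quality was not tested for this pattern. The ergosterol medians of the 3 strains ran in the order of the 3' minus 5' differences. By these differences 62A (1.89) lay between the reference arrays (1.90 and 1.84) with a median of −0.32. By the ACT1 pair, however, 62A (1.49) lay above both reference arrays (1.40 and 1.27), so RNA quality stays open. A genetic difference of the strains was not tested.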

How the results depend on the processing

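The hybridization-control block was chosen after seeing the data, and all other alternatives were planned. Over the alternatives fixed in advance, list shifts kept their side of the threshold in 1533 cases, lost the threshold in 69, gained it in 25 and turned sign after passing in 1, and named genes in 3012, 344, 119 and 0 cases. Sign turns of results that passed in neither setting were not counted. The reversal was the cell wall list of the evolved class, whose median was −0.00923 without reference replicate 2 and up to 0.0186 (without 62C); its cause was not tested. Counts stayed within 1.5 times in 121 of 186 cases. For the evolved class (107 up, 152 down), counts were 250 and 408 with all 6 arrays separate, 10 and 11 with strain as a random block, 980 and 1485 with the spread of replicate pairs, 53 and 99 with all probe sets, 1 and 1 at 0.01, and 17 and 6 with a 2-fold minimum. Leaving out an array gave 0 to 139 up and 0 to 169 down, with 0 without either reference array, when 1 reference array remained. At 0.01 62A gave 313 and 336, 62B 735 down and 62C 747 down; a 2-fold minimum gave 48 and 3, 19 and 22, and 89 and 13. The F count was 892 at 0.01, 72 with 2-fold and 626 to 2366 with an array left out. Differences of 62A and 62B numbered 434, 37 and 342 to 1493, of 62B and 62C 1084, 71 and 959 to 2478, and of 62A and 62C 9, 1 and 19 to 432. The 62A and 62C count was 221 with centring, 0 with all probe sets, 214 with the trend prior, and 272 with either block. With an array left out 62A gave 382 to 702 up and 445 to 1433 down, and 62B gave 589 to 1253 up and 596 to 1523 down. Stricter thresholds lower such counts by construction. Leaving out an array moved counts both ways, and the cause was not tested. Camera with an estimated correlation called 0 lists for the class and 0 for the strains. That outcome owes much to the few residual degrees of freedom and not to the correlation alone. Glycolysis in 62B had an estimated correlation of −0.0195, below the preset 0.01, yet its unadjusted camera p went from 0.000516 to 0.0651.

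The block fits of the class took all 6 arrays as separate, so their counts compare with 250 and 408, although the tallies above set them beside 107 and 152. The replicate block lowered these to 92 and 119, and 187 of those genes were among the 259. Deviations of same-numbered arrays correlated at −0.0595 in the single comparison possible (62B and reference), so the numbers were not taken to pair the arrays. The hybridization-control block lowered them to 74 and 118. Low signal limits the GAL genes other than GAL80, whose reference levels of 5.28 to 5.75 lay near the background of 5.07.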

Other observations

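Both tests here were chosen after the result was seen, and the genes were picked outside the rule for named genes. In 62B, genes of the kynurenine pathway, which makes NAD from tryptophan, were lower together. BNA1 had a log2 change of −0.95, BNA6 of −0.54, BNA4 of −0.38 and BNA7 of −0.16 in 62B, and all 4 passed the threshold in limma. BNA2 and BNA5, which had drawn attention to the pathway, were changed by −1.64 and −1.39. The 62B arrays also had the highest 3' minus 5' control differences (2.01 and 2.05, against 1.73 to 1.90 on the others), and RNA quality was not tested for these genes. In 62A and 62C BNA1 had changes of −0.04 and 0.07, BNA4 of −0.23 and −0.24, BNA6 of −0.19 and −0.10 and BNA7 of −0.11 and −0.11, so BNA4, BNA6 and BNA7 were below 0 there too.

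A candidate explanation for BNA2 and BNA5 is a fall shared by the pathway. It was tested on the 4 other genes, whose median of −0.46 lay at the 0.09th percentile of 10000 random lists matched on expression. A fall shared by the amino acid permease genes as a group was tested in the same way over the 3 strains. The 7 genes AGP1, CAN1, HIP1, LYP1, PTR2, TAT1 and TAT2 all had changes below 0, but 0 of them passed the threshold in limma. Their median of −0.18 lay at the 4.37th percentile, inside the range of random lists. PTR2 (−0.10) is a peptide transporter and not an amino acid permease. The list was not tested without it, so the result decides nothing about the amino acid permeases. With BAP2, BAP3, DIP5, GNP1 and MUP1, which had prompted the question, the median of 12 genes was −0.42, lower than in any of the random lists. Those added genes were chosen after their values were seen, so that median is no test of the group.

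The bacterial hybridization controls bioC and bioD read 8.85 on 62B replicate 1 and 8.82 on reference replicate 1, against 9.13 to 9.33 on the other 4 arrays.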
